A study of Mus musculus with 8 samples.

How the data were processed

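ATAC-seq, in which Tn5 transposase inserts adapters into accessible DNA, was carried out on mouse pro-B cells transformed with Abelson murine leukaemia virus. In the 2 lines, EBF1-dTAG_C and EBF1-dTAG_N, per the labels, endogenous EBF1 was replaced by a modified version, and the names give it a dTAG degron, a tag through which the compound dTAG-13 directs a protein to degradation. Each line was treated for 6 h with 0.5 uM dTAG-13 or with DMSO, the solvent control, with 2 libraries per condition and 8 libraries in all, which the series describes as biological replicates. The sample titles call the controls 0 h, whereas the treatment label gives them 6 h of DMSO; the treatment label was followed. Samples were grouped by line and treatment from the titles.

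The submitters' processing notes name Bowtie2 2.3.5.1, SAMtools 1.10, deepTools 3.3.2, MACS2 2.2.7.1 and edgeR 3.32.0 and the GRCm38 (mm10) build, without saying how each was used. Read filters, the shift of Tn5 insertion sites and the scaling of libraries are not given in the sources used here. The deposited peak lists were called per library, 1 list per sample, and hold for each peak a score, a fold enrichment at the summit over the local background of the same library, and −log10 p-values and q-values. These per-peak values are the authors' and served only to describe, rank or filter peaks within a list. For each line the authors deposited a table of their comparison of dTAG-13 with DMSO over peak regions, with log2 fold changes, mean abundance as log2 CPM, an F score, a p-value and a Benjamini-Hochberg adjusted p-value. Per the labels, edgeR is the tool of these tables, and an F with 1 numerator degree of freedom is what its quasi-likelihood test writes. The tables hold no values per library, so no test of regions was refitted and no standard error or n is attached to a region. Adjusted p-values and folds of regions are those of the authors' deposited tables throughout.

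Repeated entries (8 in the EBF1-dTAG_C table, 12 in the EBF1-dTAG_N table) were counted once, which left 54239 and 55193 regions. The deposited adjusted p-values were recomputed exactly from the deposited p-values over these regions. The direction of the log2 fold change was checked against the peak lists. Of regions with a peak in both DMSO lists and in neither dTAG-13 list, 92.6% (EBF1-dTAG_C) and 96.7% (EBF1-dTAG_N) had a negative fold. Of regions with the opposite pattern, 94.9% and 97.8% had a positive fold, so that positive means more accessible after dTAG-13. From F and p-value the denominator degrees of freedom of the deposited test were 11.2 in EBF1-dTAG_C and 110386 in EBF1-dTAG_N (median over 2000 regions each). So large a number from 4 libraries means that the spread in EBF1-dTAG_N was pooled over regions. Its p-values do not rest on replicate spread at the single region and are not comparable with those of EBF1-dTAG_C.

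A region was called changed at a deposited adjusted p under 0.05, and changes with an absolute log2 fold change of at least 1 were counted apart. Regions of the tables were paired by an overlap of at least 1 bp. Overlaps of calls were compared with independent lists of the same sizes by Fisher's exact test (two-sided). The approximate standard error of a log2 fold change was taken as its absolute value over the square root of F. It served for centring folds on the median of each table and for an approximate test of the difference between the lines. Peak numbers were compared by exact permutation tests (two-sided), within each line and over both lines with labels permuted within the line. With 2 libraries against 2 the smallest p is 0.333, and over both lines, with 36 arrangements, it is 0.0556.

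Gene spans came from the RefSeq table of GRCm38.p6, the build of the files, with 21900 protein-coding genes. This table gives gene starts and ends without strand, exons or UTRs, so a transcription start site could not be told from a gene end. Regions were therefore assigned to the nearest protein-coding gene span within 100 kb (94.4% of EBF1-dTAG_C and 93.8% of EBF1-dTAG_N regions). A region with its centre within 1 kb of either end of a protein-coding gene was called near a gene boundary, in place of the promoter class that had been planned. Near-boundary shares were compared with all other tested regions by Fisher's exact test. For 10 gene lists with 168 different genes, all of which matched the table, the number of genes with a falling or a rising region was set against 10000 random gene lists matched on regions per gene. The p-values, of which the smallest possible is 1e-04, were adjusted over 40 tests. This test was tested on simulated data with the 14470 genes of the EBF1-dTAG_C table, where 3.33% of 60 null lists passed 0.05 and 100% of 30 enriched lists were recovered.

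The depth of the libraries in reads is unknown. The summit pileup and the background of a peak were solved from the deposited fold enrichment and −log10 p-value (relative tolerance 1e-04), which succeeded for 99.7% to 99.99% of peaks per library and for 99.97% of 3000 simulated peaks. The lowest background pileup gives relative depth only.

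Before the data were examined, the groups, tests, gene lists and the rule for named genes were fixed. That rule ranks called regions of each line by adjusted p (ties by the larger fold). Near a gene means that the gene is the nearest within 100 kb. The rule names the genes of the first 8 falling and first 8 rising regions, 1 region per gene, and up to 6 called members of each list per line. Ebf1, Cd79a, Igll1 and Pax5 are named whatever their value. Genes with Gm or Rik names (0 met) and regions with no gene (1 met) were passed over. Genes named outside the rule are marked as chosen after their values were seen. Because the tables hold the comparison only, the planned count fits, the fit with a replicate block, the interaction model and the rotation test of lists were not run. Motif analysis, which needs the genome sequence, was not run. Alternatives tried were other thresholds, abundance filters, overlaps, distances, peak cut-offs and leaving out peak lists; centring, other degrees of freedom, other matching of lists, a boundary comparison with regions not called, the receptor locus tests and the approximate line test were added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6; figures used matplotlib 3.10.9.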

Results

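EBF1 is a transcription factor that specifies the B cell lineage. Chromatin accessibility was measured in EBF1-dTAG_C and EBF1-dTAG_N pro-B cells after 6 h with dTAG-13 or DMSO, to ask which accessible regions change once EBF1 is degraded. There were 4 groups of 2 libraries. The loss of EBF1 protein itself cannot be read from ATAC-seq and was not measured here. Relative depth, as the lowest background pileup, was 0.337 ± 0.00937 (SD, n = 2) in the EBF1-dTAG_C DMSO libraries and 0.244 ± 0.0204 (SD, n = 2) after dTAG-13. In EBF1-dTAG_N it was 0.405 ± 0.00552 (SD, n = 2) with DMSO and 0.360 ± 0.0171 (SD, n = 2) after dTAG-13. The background pileup of the dTAG-13 libraries was thus lower in both lines, by 27.8% in EBF1-dTAG_C. Replicate peak lists overlapped each other for 76.8% to 86.3% of their peaks and shared only 237 to 376 identical intervals, so replicate lists are not copies of each other.

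Fewer peaks were called after dTAG-13 in both lines. In EBF1-dTAG_C the number was 41289.5 ± 1201 (SD, n = 2) with DMSO and 34292 ± 127 (SD, n = 2) after dTAG-13, a change of -16.9%. In EBF1-dTAG_N it was 40889.5 ± 1023 (SD, n = 2) and 37786 ± 2736.5 (SD, n = 2), a change of -7.59%. The EBF1-dTAG_N difference, -3103.5 peaks, was -1168.5 without dTAG-13 replicate 1 and -5038.5 without dTAG-13 replicate 2. With peaks of −log10 q of at least 5 the changes were -14.0% in EBF1-dTAG_C and -12.9% in EBF1-dTAG_N, and at 10 they were -18.1% and -17.3%. Both dTAG-13 libraries lay below both DMSO libraries in each line, which gives an exact permutation p = 0.333 within a line and p = 0.0556 over both lines, the smallest that these designs allow. In EBF1-dTAG_C, 4650 peaks were present in both DMSO lists and in neither dTAG-13 list, against 764 with the reverse pattern. In EBF1-dTAG_N these numbers were 5733 and 1971. Without dTAG-13 replicate 1 they were 6792 and 6884. A dTAG-13-only peak then needed 1 list and a DMSO-only peak still 2, so this turn does not show that the excess was lost. The other ways of pairing the 4 lists of a line gave 719 to 1471 peaks in EBF1-dTAG_C and 514 to 1126 in EBF1-dTAG_N. With equal numbers of best peaks per list, the counts were 2963 and 1572 in EBF1-dTAG_C and 4531 and 2545 in EBF1-dTAG_N.

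**Figure D1:**
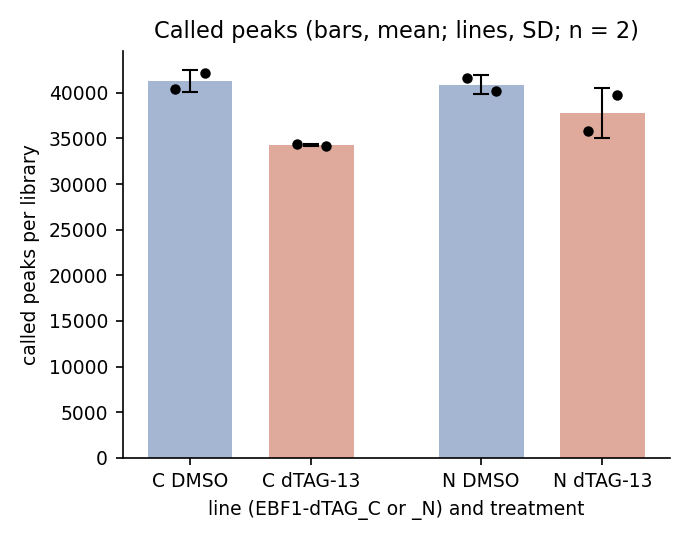
Called peaks per library (vertical axis, number of peaks) by line and treatment; points are libraries, bars the mean and vertical lines the SD (n = 2). All 4 dTAG-13 libraries (34202 to 39721 peaks) lie below all 4 DMSO libraries (40166 to 42139 peaks).

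In EBF1-dTAG_C, accessibility was lost far more often than gained. A region 65 kb outside Med13l, which encodes a subunit of the Mediator kinase module, had the smallest adjusted p among named falling regions, and was 8.52-fold lower after dTAG-13 in the authors' deposited table (chromosome 5, 118494657 to 118495660, GRCm38; adjusted p = 1.27e-07). Regions inside Hnrnpl, an RNA-binding protein gene, and Zdhhc7, a palmitoyltransferase gene, fell 9.38-fold and 18.6-fold in the authors' deposited table (adjusted p = 8.63e-07 and 1.09e-06). The authors' deposited table gave a 53.7-fold fall inside Adap1, where both DMSO lists and neither dTAG-13 list held a peak. Falls of 11.2-fold near Asb2, 7.83-fold near Lemd2 and 5.29-fold near the syndecan gene Sdc4, and of -4.64 on the log2 scale near the sorting nexin gene Snx5, complete the first 8 of the authors' deposited table, with adjusted p of at most 1.43e-06.

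Regions near genes of the early B cell programme were among those that fell in EBF1-dTAG_C. At Igll1, which encodes the lambda 5 part of the surrogate light chain, a region 137 bp outside the gene (chromosome 16, 16863837 to 16864407) was 7.59-fold lower in the authors' deposited table (adjusted p = 4.01e-06). The surrogate light chain gene Vpreb2 had a region at -2.35 on the log2 scale, and the interleukin 7 receptor gene Il7r had a region 3.91-fold lower, in the authors' deposited table (adjusted p = 3.18e-06 and 6.94e-05). The authors' deposited table also lists falls of 7.11-fold inside Cplx2, 2.65-fold inside Bst1 and 8.19-fold near the transcription factor gene Lef1. Inside Ebf1 itself, 1 region (chromosome 11, 45001928 to 45002341) fell, with -1.72 on the log2 scale in the authors' deposited table (adjusted p = 0.0124), and 3 of its 31 regions fell. Cd79a, a signalling chain of the B cell receptor, had a region 69 bp outside the gene that was 1.49-fold lower, and an internal region of the B cell factor gene Pax5 was 1.69-fold lower, in the authors' deposited table (adjusted p = 0.0143 and 0.00824).

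Rises in EBF1-dTAG_C were few and small. The rising region with the smallest adjusted p lay 25 kb from Col19a1 (chromosome 1, 24612573 to 24613317). It was 1.41-fold higher in the authors' deposited table (adjusted p = 0.000740), with a mean abundance of 12.16 on the log2 CPM scale, the highest in that table; the origin of its reads was not analysed here. Near Arl4c the rise was 2.11-fold, inside Rapgef1 2.98-fold, near the chromogranin gene Chga 2.27-fold and inside Septin9 1.82-fold in the authors' deposited table. Counted over all their regions in EBF1-dTAG_C, 4 rose and 3 fell for Septin9, and 2 rose and 1 fell for Rapgef1. The authors' deposited table gave 2.81-fold inside the deubiquitinase gene Usp3, 1.59-fold at a region 93 kb from Id2, an inhibitor of E proteins, and 2.10-fold near Cd1d1, which encodes a lipid antigen-presenting molecule (adjusted p from 0.00640 to 0.00736 for Septin9 to Cd1d1).

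Of 54239 regions in the authors' deposited table for EBF1-dTAG_C, 3593 (6.62%) fell and 167 rose. The median fall in the authors' deposited table was -2.26 on the log2 scale (4.78-fold) and the median rise 0.94 (1.92-fold); 3324 falls and 76 rises reached an absolute log2 fold change of 1. Of the falling regions, 54.0% had a peak in both DMSO lists and in neither dTAG-13 list. Folds of the authors' deposited table centred on their median (0.09 on the log2 scale) gave 4007 falls and 88 rises.

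In EBF1-dTAG_N, many of the same loci held a region that lost accessibility. The EBF1-dTAG_N test pooled the spread over regions, so its adjusted p-values are not comparable with those of EBF1-dTAG_C. The Zdhhc7 region was 19.0-fold lower and the Hnrnpl region 12.8-fold lower in the authors' deposited table, both with an adjusted p listed at 0. Folds of 9.93 at Fetub, 8.81 at Lemd2, 6.48 at Palm, 6.46 at Med13l and 5.67 at Lhpp followed among the falls of the authors' deposited table, all with an adjusted p listed at 0. A region at Igll1 was 8.30-fold lower in the authors' deposited table (adjusted p = 3.50e-314). Regions near Il7r and inside Fcrla, an Fc receptor-like gene, were 8.50-fold and 39.2-fold lower (adjusted p = 5.85e-111 and 1.28e-79). The Ebf1 region overlapping that of EBF1-dTAG_C was 9.90-fold lower (adjusted p = 1.08e-58 in the authors' deposited table), while 3 of the 27 Ebf1 regions fell and 6 rose. In the same authors' deposited table an internal Pax5 region was 1.65-fold lower (adjusted p = 2.41e-07). The fall at Cd79a was 1.14-fold in the authors' deposited table (adjusted p = 0.0410), and read against the degrees of freedom of the EBF1-dTAG_C table its adjusted p was 0.0908.

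Rises in EBF1-dTAG_N were smaller than falls, and as many on the deposited scale only (4403 rises and 11454 falls on centred folds). Inside Septin9 a region (chromosome 11, 117320487 to 117320871) was 2.79-fold higher in the authors' deposited table (adjusted p = 1.06e-35). The authors' deposited table ranked next the regions near Plpp3 (2.98-fold), near Moxd2 (2.40-fold), inside the two-pore channel gene Tpcn1 (4.22-fold) and near Id2 (1.99-fold). The zinc transporter gene Slc39a10 followed with a 4.18-fold rise, Arhgef2 with 1.14 on the log2 scale and Cd93 with 8.73-fold in the authors' deposited table (adjusted p from 3.02e-31 to 4.00e-28). At Cd93, both dTAG-13 lists and neither DMSO list held a peak. Counted over all their regions in EBF1-dTAG_N, 9 rose and 8 fell for Septin9, and 2 rose and 4 fell for Tpcn1. The other genes of this paragraph had more rising than falling regions.

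Of 55193 regions in the authors' deposited table for EBF1-dTAG_N, 10190 (18.5%) fell and 10383 (18.8%) rose. The median fall of the authors' deposited table was -2.04 on the log2 scale (4.11-fold) and the median rise 0.63 (1.55-fold); 8243 falls and 2833 rises reached an absolute log2 fold change of 1. The median of all folds in this authors' deposited table was 0.17 on the log2 scale, and centring on it gave 11454 falls and 4403 rises, so that the share of falls among calls was 49.5% as deposited and 72.2% centred. Read against the degrees of freedom of the EBF1-dTAG_C table, the F values of the authors' deposited table gave 9002 falls and 6848 rises.

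**Figure D2:**
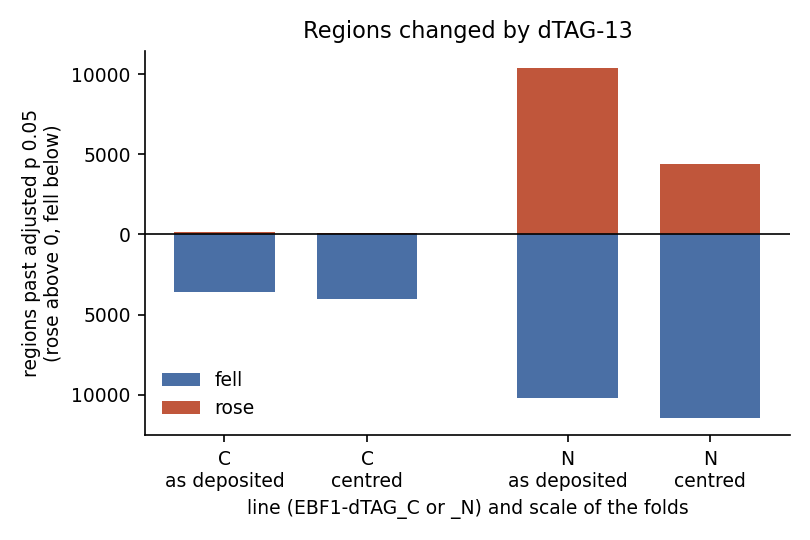
Number of regions past an adjusted p of 0.05 (vertical axis; rises above 0, falls below) in EBF1-dTAG_C and EBF1-dTAG_N, with folds as in the authors' deposited tables and with folds centred on the median of each table. In EBF1-dTAG_N, 10383 rises become 4403 on centring and 10190 falls become 11454.

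The B lineage target list, fixed from general knowledge of EBF1, had falling regions at more genes than matched random lists did. In EBF1-dTAG_C, 23 of its 29 measured genes had a falling region, against 10.1 in matched random lists (adjusted p = 0.0010 by permutation); in EBF1-dTAG_N it was 28 of 30, against 17.7 (adjusted p = 0.0010). Adjusted over the list alone, 26 and 28 genes had a falling region. All 4 regions of Vpreb3, a gene chosen after its values were seen, and all 3 of Fcrla fell in EBF1-dTAG_N. In EBF1-dTAG_C, 1 of 4 Vpreb3 regions and 2 of 3 Fcrla regions fell. Arid3a, also chosen after its values were seen, had 1 falling and 5 rising regions in EBF1-dTAG_N. Of the target list, 6 genes in EBF1-dTAG_C had no called region, while in EBF1-dTAG_N 14 genes had a rising region, against 18.0 in random lists. The list of pre-B cell receptor signalling genes, which shares 13 genes with the target list, gave 20 of 24 genes in EBF1-dTAG_C (8.66 in random lists) and 23 of 24 in EBF1-dTAG_N (14.3 in random lists), each at an adjusted permutation p = 0.0010. Adjusted over the list alone, these were 23 and 23 genes. Its members with the smallest adjusted p in EBF1-dTAG_C included Pik3cd, a PI3 kinase subunit gene (4.76-fold lower), Pik3ap1 (2.68-fold lower) and the phospholipase gene Plcg2 (3.82-fold lower) in the authors' deposited table. In EBF1-dTAG_N, a region of the exchange factor gene Vav1 was 14.5-fold lower and a Plcg2 region 5.35-fold lower in the authors' deposited table. Folds given here for a gene are those of its best-ranked region. In EBF1-dTAG_N, 4 Vav1 regions fell and 3 rose, and 5 Plcg2 regions fell and 4 rose.

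Genes of B lineage transcription factors often had a falling region, but the list did not pass the test against matched random lists after adjustment. There were 16 of 24 such genes in EBF1-dTAG_C (adjusted p = 0.306 by permutation) and 23 of 24 in EBF1-dTAG_N (adjusted p = 0.274 by permutation); adjusted over the list alone, there were 17 and 23. With regions assigned within 20 kb the EBF1-dTAG_N value was adjusted p = 0.0380. Named falls in EBF1-dTAG_C were 3.89-fold inside Tcf3, which encodes E2A, 20.3-fold near Runx1, 1.77-fold near the coactivator gene Pou2af1, 2.61-fold near Bcl11a and 7.74-fold near Id3 in the authors' deposited table. In EBF1-dTAG_N, Irf4, Foxo1 and Irf8 had regions 8.92-fold, 4.95-fold and 3.69-fold lower in the authors' deposited table. The authors' deposited table for EBF1-dTAG_N listed a region 2.94-fold lower inside Tcf3, 1 at 2.89-fold lower near Bcl11a and 1 at 4.22-fold lower near Lef1. In EBF1-dTAG_N, 3 Bcl11a regions fell and 4 rose. For Irf4, 1 fell and 2 rose, for Irf8, 7 fell and 3 rose, and for Foxo1, 8 fell and 0 rose. For Tcf3, 4 fell and 0 rose, and for Lef1, 6 fell and 1 rose.

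Among proliferation and kinase pathway genes, 20 of 20 had a rising region in EBF1-dTAG_N, against 13.9 in random lists (adjusted p = 0.0032 by permutation), and 20 adjusted over the list alone. On centred folds it was 12 of 20 (adjusted p = 0.334), so the call rests on the scale of the folds. In EBF1-dTAG_C none of the 20 had a rising region (0.669 in random lists). The number with a falling region was 8 of 20 in EBF1-dTAG_C and 12 of 20 in EBF1-dTAG_N (8.49 and 14.4 in random lists; adjusted permutation p = 1.0 for each). The cytokine-induced gene Cish had a region 1.80-fold higher in EBF1-dTAG_N in the authors' deposited table. Falls in EBF1-dTAG_C were 5.95-fold inside Ccnd3, the cyclin D3 gene, 99.4-fold near Ccnd1, 2.27-fold inside the survival gene Bcl2l1 and 2.54-fold inside Abl1 in the authors' deposited table. The Ccnd1 region, the only 1 of 8 that fell, lay 97609 bp from the gene. Its mean abundance was 2.34 on the log2 CPM scale, and neither dTAG-13 list held a peak there. The overlapping region of EBF1-dTAG_N was at -4.55 on the log2 fold scale. The authors' deposited table for EBF1-dTAG_N gave 4.61-fold lower inside Ccnd3, 2.69-fold lower inside Bcl2l1 and a fall of -2.32 on the log2 scale inside Cdk6. Of the regions of these genes in EBF1-dTAG_N, 5 fell and 4 rose for Ccnd3, 6 and 1 for Bcl2l1, and 2 and 3 for Cdk6.

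**Figure D3:**
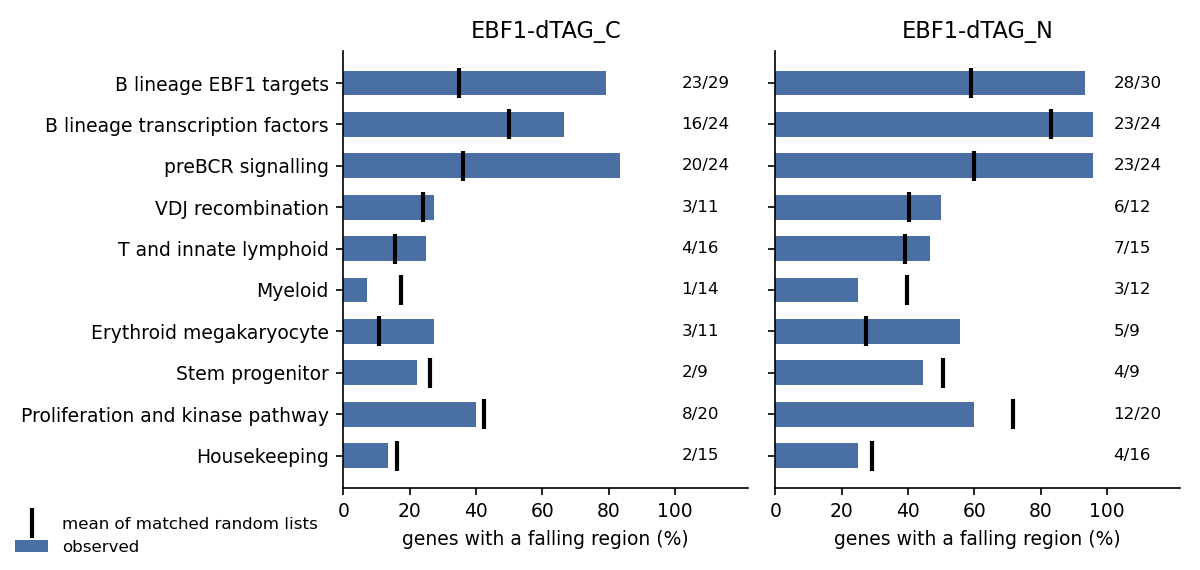
Share of the measured genes of each list that had a falling region (horizontal axis, percent; counts at the right) in EBF1-dTAG_C and EBF1-dTAG_N; black ticks are the mean of 10000 random lists matched on regions per gene. B lineage targets (23 of 29 and 28 of 30) and pre-B cell receptor genes (20 of 24 and 23 of 24) lie furthest right of their ticks.

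Lists for other cell types and functions did not pass the test in either direction. Genes with a falling region in EBF1-dTAG_C and EBF1-dTAG_N were 4 of 16 and 7 of 15 for T and innate lymphoid markers (adjusted permutation p = 0.650 and 0.884). They were 1 of 14 and 3 of 12 for myeloid markers (p = 1.0 for both by permutation, adjusted), 3 of 11 and 5 of 9 for erythroid and megakaryocyte markers (adjusted permutation p = 0.400 and 0.274), and 2 of 9 and 4 of 9 for stem and progenitor genes (p = 1.0 for both by permutation, adjusted). For V(D)J recombination the counts were 3 of 11 and 6 of 12 (adjusted permutation p = 1.0 and 0.870), and for housekeeping genes 2 of 15 and 4 of 16 (p = 1.0 for both by permutation, adjusted). Adjusted over the list alone, falling counts were 5 and 7 (T and innate), 1 and 3 (myeloid), 3 and 5 (erythroid), 2 and 4 (stem), 3 and 7 (recombination) and 2 and 4 (housekeeping). Rising regions in EBF1-dTAG_N were found for 5 T and innate, 6 myeloid, 3 erythroid, 4 stem, 7 recombination and 7 housekeeping genes, and for 20 transcription factor and 12 pre-B cell receptor genes of the lists above. In EBF1-dTAG_C, 1 gene each of the target, transcription factor, pre-B cell receptor, T and innate and housekeeping lists had a rising region, and 0 genes of the other lists did. Single regions still moved: Tcf7, a T cell factor gene, had a region 7.82-fold lower in EBF1-dTAG_C, and Erg, an ETS factor gene, had a region 7.91-fold lower, in the authors' deposited table. In the authors' deposited table for EBF1-dTAG_N, a region 65 kb from Cebpb was 10.1-fold lower. There, the recombinase gene Rag1 had a region 2.87-fold lower and the Fc receptor gene Fcgr3 a region 4.43-fold higher. Regions at Gapdh, Polr2a and Eef1a1 were 1.28-fold, 1.23-fold and 1.20-fold higher in the authors' deposited table for EBF1-dTAG_N, and none of them passed on centred folds (adjusted p = 0.101, 0.158 and 0.478). Of the same housekeeping list, a region near Actb was 20.7-fold lower in EBF1-dTAG_C and 24.9-fold lower in EBF1-dTAG_N. A region near Ywhaz was 9.13-fold and 11.8-fold lower, and these falls stayed called on centred folds.

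The lines were compared next, since they carry a degradable EBF1 in different forms and share no control libraries. Of 42803 regions found in both of the authors' deposited tables, 3453 fell in EBF1-dTAG_C, 7222 fell in EBF1-dTAG_N and 3415 fell in both, where independent lists would share 583 (odds ratio 839; Fisher's exact p too small for the software to hold). This is 98.9% of the EBF1-dTAG_C falls that have a partner, and 47.3% of those of EBF1-dTAG_N. Rises overlapped at 131 regions of 148 in EBF1-dTAG_C and 9358 in EBF1-dTAG_N, with 32.4 for independent lists (Fisher's exact p = 2.17e-67); 65 of them were found on centred folds. They included the regions at Septin9, Id2, Arl4c, Chga, Usp3, Cd1d1 and Col19a1, of which the last was 0.13 on the log2 scale in the authors' deposited table for EBF1-dTAG_N and lies below the median of that table. No region was called in opposite directions (1 on centred folds). Log2 fold changes of the authors' deposited tables correlated across regions with Pearson r = 0.840 and Spearman rho = 0.645. Over regions called in neither line Pearson r was 0.361, and 76.8% of all paired regions had the same sign. Regions are not independent replicates. At regions that fell in both, the median was -2.25 in EBF1-dTAG_C and -2.36 in EBF1-dTAG_N on the log2 scale of the authors' deposited tables.

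**Figure D4:**
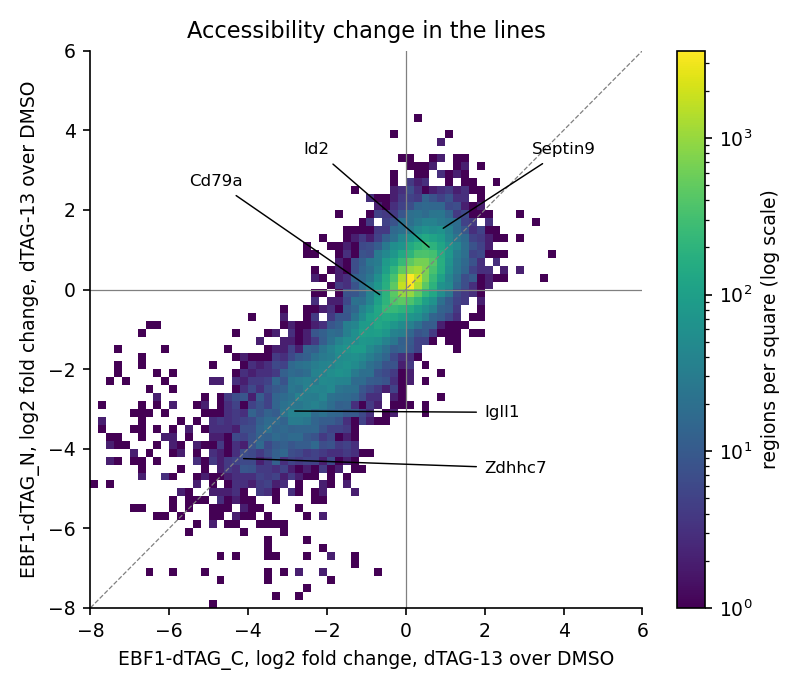
Log2 fold change, dTAG-13 over DMSO, in EBF1-dTAG_C (horizontal axis) and EBF1-dTAG_N (vertical axis) for 42791 regions of both of the authors' deposited tables; colour gives regions per square of 0.2 by 0.2 on a log scale, the dashed line marks equal folds, and 12 regions lie outside the axes. Over all 42803 paired regions Pearson r was 0.840, and over those called in neither line 0.361. The labelled regions of Igll1 and Zdhhc7 lie low and those of Septin9 and Id2 high in both lines.

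Some folds differed in size between the lines, among them Ebf1 (-1.72 and -3.31 on the log2 scale in the authors' deposited tables for EBF1-dTAG_C and EBF1-dTAG_N) and Il7r (-1.97 and -3.09). An approximate t test of the difference, with standard errors derived from fold and F, called 0 of 42803 regions at an adjusted p of 0.05, and 1711 at an unadjusted p of 0.05, which is 4.0% and below the 5% expected by chance. With a normal reference in place of t it called 67. A call in EBF1-dTAG_N without a call in EBF1-dTAG_C therefore does not show that the lines differed at that region.

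Regions that fell lay away from gene ends. In EBF1-dTAG_C, 6.62% of falling regions were within 1 kb of a gene boundary, against 21.8% of all other tested regions (odds ratio 0.254; Fisher's exact p = 3.94e-130); in EBF1-dTAG_N it was 7.70% against 23.6% (odds ratio 0.271). Their median distance to a gene boundary was 15.9 kb in EBF1-dTAG_C and 16.0 kb in EBF1-dTAG_N. Rising regions were near a boundary in 6.59% of cases in EBF1-dTAG_C (odds ratio 0.268; Fisher's exact p = 7.17e-07) and in 29.7% in EBF1-dTAG_N, against 18.5% of all other regions (odds ratio 1.86; Fisher's exact p = 1.92e-132). On centred folds the EBF1-dTAG_N share was 11.3% and the odds ratio turned to 0.467, and among rises of at least 1 on the log2 scale the shares were 3.95% in EBF1-dTAG_C and 4.94% in EBF1-dTAG_N. Among the named falling regions of EBF1-dTAG_C, those of Igll1, Cd79a, Pou2af1, Zdhhc7, Hnrnpl, Pik3ap1, Plcg2 and Nfe2 lay within 1 kb of a gene boundary, and those of Med13l, Lemd2, Runx1, Lef1, Pim1, Ccnd1 and Erg over 50 kb from it.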

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

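Tests of library scaling, of the degrees of freedom, of the standard errors, of the boundary shares and of the fold difference between the lines, the random draws for rises in EBF1-dTAG_N, and the reading of the peak loss by line and by pairing, were chosen after the result was seen; the others were set down before their results were seen.

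Rising regions were within 1 kb of a gene boundary in 29.7% of 10383 cases in EBF1-dTAG_N and in 6.59% of 167 in EBF1-dTAG_C (odds ratio 5.99; Fisher's exact p = 2.53e-13, over regions, which are not independent). On centred folds the shares were 11.3% and 3.41% (odds ratio 3.61; Fisher's exact p = 0.0156). Among rises of at least 1 on the log2 scale they were 4.94% and 3.95%, and among smaller rises 39.0% and 8.79%. The lists were called at unlike power, so these shares do not show that dTAG-13 acted differently in the lines. Groups of 2 libraries are too small to test for a library that stands apart.

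More regions rose than fell in EBF1-dTAG_N, where EBF1-dTAG_C had few rises. Rises made in EBF1-dTAG_N alone by its own libraries are argued against as the source of all the rises. Of the 9358 rising regions that have a partner in EBF1-dTAG_C, 77.9% lay above the median fold there. Random draws (1000) of paired regions that did not fall in EBF1-dTAG_N gave 58.2% to 60.7%. They were matched on abundance and distance to a gene boundary. The excess does not tell how many rises were made in EBF1-dTAG_N alone, and 1.40% of the 9358 were called in EBF1-dTAG_C. Centring ended 57.6% of the rising calls, among them those at Gapdh, Polr2a and Eef1a1, but taking a constant from every fold ends small rises whatever their cause, so that scaling of the libraries and a real excess of small rises cannot be told apart. Many small rises at abundant regions may account for the excess near gene boundaries: among rises of at least 1 on the log2 scale 4.94% were near a boundary, against 39.0% of smaller rises. The 4403 rises left on centring, such as those at Septin9, Cd93 and Id2, stay open; the approximate t test of the difference between the lines called 0 of 42803 regions at an adjusted p of 0.05 and 1711 at an unadjusted p of 0.05 (67 adjusted with a normal reference), which does not show that the lines were alike.

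More regions were called in EBF1-dTAG_N than in EBF1-dTAG_C. Read against the degrees of freedom of EBF1-dTAG_C, its F values still gave 4.22 times as many calls as in EBF1-dTAG_C. The reference degrees of freedom alone are thus argued against as the whole cause. The pooling of the spread over regions also sets F, which was left as deposited. Pooling as the cause is therefore not argued against. A smaller spread estimate in its test may be a cause, with approximate standard errors at 0.715 of those of EBF1-dTAG_C at the median. This is close to a restatement of the larger number of calls. Such errors come from fold and F and do not measure the spread between libraries. Peak numbers had a larger pooled SD between replicates in EBF1-dTAG_N (2066 peaks) than in EBF1-dTAG_C (854 peaks). This came from the dTAG-13 libraries (SD 2736.5 and 127 peaks, n = 2 each). With DMSO the SD was 1023 peaks in EBF1-dTAG_N and 1201 in EBF1-dTAG_C (n = 2 each). Relative depth was also higher in EBF1-dTAG_N, and its part was not tested. Of the 3453 falls in EBF1-dTAG_C with a partner, 98.9% were also called in EBF1-dTAG_N. Whether EBF1 was lost more fully in either line cannot be read from these data.

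Fewer peaks were called after dTAG-13. In EBF1-dTAG_N, falling regions carried 168% of the net loss of peaks (101% to 615% over the pairings of a DMSO with a dTAG-13 library). Loss at these regions may account for it, but they were called from the same libraries, so that a large share is close to given. Regions not called as changed carried -17.9%, with a range of -296% to 24.0% that leaves a part for depth open. Because far more regions were called in EBF1-dTAG_N, such shares are not comparable between the lines. In EBF1-dTAG_C, regions not called carried 66.9% (63.2% to 69.8%), as lower depth would give. Falling regions carried 33.6% there, and how far loss at such regions adds to depth cannot be told apart, since not-called regions held losses both where EBF1-dTAG_N fell (23.3%) and where it was not called (29.2%) or had no partner (16.1%). Read over both lines together, neither explanation met its bound.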

How the results depend on the processing

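Centring, other degrees of freedom, the line test, comparison with not-called regions and other matching or boundary assignment of genes were chosen after the data were seen. No paired analysis was possible because the tables hold no values per library, the labels do not say that replicate numbers mark anything shared, and peak names inside 2 EBF1-dTAG_C lists carry other replicate numbers (4 in the list of DMSO replicate 1, 3 in that of dTAG-13 replicate 2); by number alone, peak numbers differed by -6058 and -7937 in EBF1-dTAG_C and by -5762 and -445 in EBF1-dTAG_N. Not run for want of counts were DESeq2, library size scaling, the replicate block, leaving libraries out of the tables, pseudocounts and a refit; the authors' annotation and motifs were not used here. Depth in reads is unknown, so it sets no floor here. Of 305 alternative values for summary results 267 held, as did 505 of 514 for named regions. The other 9 values for named regions kept their direction and lost the call. Most of the 305 were gene list tests, and most of those lists did not pass in the main setting either. Most named regions were chosen for a small adjusted p, so these shares do not measure robustness. To hold meant the same side of the threshold for a test, within 1.5 times for a count, and within 1 SD between replicates for the change in peak number, a wide bound in EBF1-dTAG_N (2066 peaks, against 854 in EBF1-dTAG_C).

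Stricter or looser thresholds moved counts by construction. At an adjusted p of 0.01 there were 2284 falls and 14 rises in EBF1-dTAG_C and 6299 rises in EBF1-dTAG_N, with 2216 falls and 13 rises shared; at 0.1, EBF1-dTAG_C had 495 rises. A minimum log2 fold of 0.6 gave 147 rises in EBF1-dTAG_C and 5444 in EBF1-dTAG_N, and 1.6 gave 21 and 895. Above the median abundance EBF1-dTAG_N had 5778 falls, with fewer regions tested. Centring left 88 and 4403 rises (41 and 1569 of at least 1 on the log2 scale) and 65 shared; degrees of freedom of EBF1-dTAG_C left 6848 rises in EBF1-dTAG_N, and 2534 with centring. Centring also turned the boundary odds ratio of EBF1-dTAG_N rises to 0.467 and left 12 proliferation genes with a rise (adjusted permutation p = 0.334). Within 20 kb, 23 B lineage transcription factor genes had a fall in EBF1-dTAG_N (adjusted permutation p = 0.0380); the cause was not tested.

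Peak numbers changed by -5342 in EBF1-dTAG_C and -5155.5 in EBF1-dTAG_N at −log10 q of at least 5, and by -5162 and -5380.5 in EBF1-dTAG_C and EBF1-dTAG_N at 10; the cause was not tested. Without each list in turn the change was -7847 to -6148 and -5038.5 to -1168.5. Equal numbers of best peaks gave 2963 DMSO-only and 1572 dTAG-13-only peaks in EBF1-dTAG_C. Leaving out a list, which loosens the criterion, gave 6753 to 10042 and 1808 to 3634 in EBF1-dTAG_C (highest without DMSO replicate 1 and without dTAG-13 replicate 2). In EBF1-dTAG_N it gave 6792 to 9326 and 3266 to 6884 (highest without DMSO replicate 2 and without dTAG-13 replicate 1). The condition that loses a list then needs a peak in 1 list, and the other condition still in 2. Leaving out dTAG-13 replicate 1 gave both the 6792 and the 6884, which are thus at unlike criteria.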

Other observations

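The tests of receptor loci were chosen after the counts of calls in them were seen; the tests of distances between regions were set down before their results were seen.

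Regions across the immunoglobulin kappa locus, which pro-B cells have not yet rearranged as a rule, lost accessibility in both lines. Of 214 regions in the locus (chromosome 6, 67555636 to 70726754) 50 fell in EBF1-dTAG_C and 0 rose in the authors' deposited table, and in EBF1-dTAG_N 103 of 244 fell and 20 rose. These shares of falls, 23.4% and 42.2%, compare with 6.62% and 18.5% of all regions (odds ratios 4.34 and 3.25; Fisher's exact adjusted p = 4.84e-14 and 2.19e-16 over 28 tests). On centred folds 53 and 109 regions fell (adjusted p = 4.68e-14 and 1.59e-15 by Fisher's exact test). At the heavy chain locus 17 of 173 and 35 of 191 regions fell (9.83% and 18.3%, odds ratios 1.54 and 0.991), and neither line passed (Fisher's exact adjusted p = 0.258 and 1.0). Regions within a locus are not independent.

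At the T cell receptor gamma locus, 2 of 11 regions rose in EBF1-dTAG_C and 8 of 16 in EBF1-dTAG_N in the authors' deposited tables (Fisher's exact adjusted p = 0.00356 and 0.0221), while on centred folds 1 and 4 rose and neither line passed (Fisher's exact adjusted p = 0.0991 and 0.135; unadjusted 0.0177 and 0.0338). In EBF1-dTAG_C these were 19182259 to 19182628 (1.72-fold higher) and 19219398 to 19220247 (1.31-fold higher, not called on centred folds) on chromosome 13 in the authors' deposited table. At the beta locus 2 of 21 regions rose in EBF1-dTAG_C (Fisher's exact adjusted p = 0.0107, and 0.135 on centred folds, where 1 rose) and 6 of 21 in EBF1-dTAG_N (adjusted p = 0.490 by Fisher's exact test); those of EBF1-dTAG_C were 40890928 to 40891404, beside Moxd2 (2.48-fold higher), and 41554298 to 41554990 (1.46-fold higher, not called on centred folds) on chromosome 6 in the authors' deposited table.

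Regions that fell in both lines lay close together. Of 3415 such regions, 48.3% had another within 50 kb, above the highest of 1000 random draws matched on abundance and distance to a gene boundary (mean 37.7%, range 34.9% to 41.6%). As a hypothesis, the loss of EBF1 may act on neighbourhoods of regions; a shared local trend of the measurement was not tested. A second hypothesis, that rises lie next to falls, was not supported. Of the 131 regions that rose in both lines, 33.6% had a shared fall within 50 kb, inside the range of the random draws (mean 39.2%, range 25.2% to 51.9%). This is the outcome set down beforehand for its absence. The range is wide with so few regions, so that a small excess stays open.

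Between the DMSO lists of the lines, 3213 peaks were present in both EBF1-dTAG_C lists and in neither EBF1-dTAG_N list, and 3566 had the reverse pattern. The genes with the most regions falling in both lines for their number of regions, chosen after their values were seen, were Col26a1 (9 of 20), Col6a6 (5 of 6) and Pax7 (5 of 6), and none passed a binomial test after adjustment (adjusted p = 0.0755 for each).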
